A study of Mus musculus with 9 samples.

How the data were processed

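The 9 libraries came from mouse E14TG2a cells, an embryonic stem cell line, and from cells derived from it. Stages were embryonic stem cells (mESC), radial-glial neuronal progenitors (NPC) and glutamatergic pyramidal neurons (NC). Nuclei carried covalent tags on unmodified CG sites (uCG), on 5-hydroxymethylcytosine at CG sites (hmC) and on GC sites that a GC-directed enzyme could reach in chromatin (GC). Libraries with all 3 tags are called 3-X and those with GC and 1 further tag 2-X. Per the labels' protocols, Ion Torrent libraries were sonicated, ligated and enriched with biotin, and Illumina libraries were made with Tn5 transposase without enrichment of the click product.

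The deposited tables hold raw read counts per site, with 1 column per library and no normalization. Per the submitters' processing notes, FastQC, cutadapt 3.4, BWA 0.7.17, SAMtools 1.9 and R 4.0.2 were used with the mm10 build; what each did, and the filters on reads and sites, are not given in the sources used here. Columns were assigned to libraries from their names, which abbreviate the platform, the labeling and the stage. That the stage codes run from mESC through NPC to NC is an inference from the order of the stages in the study's description, and every direction between stages rests on it. A pair of GC columns share a single name and could not be assigned, so 2 columns of per-sample values were not used and GC in 2-X libraries was not analysed here. The authors' region tables list intervals with a width in bp and a stage; how regions were called is not given in the sources used here.

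Sites lay on the 19 autosomes. Reads were summed over genes of the GRCm38.p6 annotation, which is the assembly of mm10. The annotation at hand gave start and end but no strand, so the transcription start of a gene was unknown and the planned promoter windows could not be drawn. In their place, the end of each gene with more CG sites within 1 kb was used, and is called the CG-rich gene end. Genes entered only where the CG number plus 1 differed between both ends by at least 1.5 times, a limit set from CG numbers before any read count was compared. This kept 14914 of 20672 genes, or 72.1%. Gene bodies ran from 1 kb inside the start to 1 kb inside the end for the 17652 genes spanning at least 3 kb. Windows of neighbouring or overlapping genes share reads, and the counts carry no strand.

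For each mark, the 6 deep 3-X libraries (1 Ion Torrent and 1 Illumina library per stage, replicates 1 and 2) were fitted together with edgeR 4.0.16, using TMM factors, filterByExpr and a quasi-likelihood F test. Terms for stage and platform left 2 residual degrees of freedom. Calls had a Benjamini-Hochberg adjusted p under 0.05. Numbers at an unadjusted p under 0.05 are given beside many counts of 0. In the main fits chance alone would give 636 of 12719 gene ends for uCG and 719 of 14385 for GC. For hmC it would give 778 of 15551 gene bodies. Numbers below these give no evidence of changes short of the threshold. Library size was the number of the mark's reads in the tested gene ends or gene bodies, not all its reads. Fold changes and CPM values are thus relative to the other gene ends or bodies, and a change shared by most of them was not measured. SE values are the log2 fold change divided by the root of F. The labels do not say that libraries of a stage came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Read depth bears on counting error only, and molecular identifiers are not named in the sources used here. Comparisons share libraries: both set against mESC share the mESC libraries, and chance deviations of the NPC libraries move NPC against mESC and NC against NPC in opposite directions.

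Before the data were examined, 11 gene lists with 291 entries were fixed, of which 279 lay on autosomes. They held markers of pluripotency, radial glia and neural progenitors, neurons and synapses, inhibitory neurons, astrocytes and oligodendrocytes, mesoderm and endoderm, and germline, imprinted, Hox, DNA methylation machinery and housekeeping genes. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry as checks. With an estimated correlation camera rested on the 2 residual degrees of freedom, so that check had little power here. For GC of pluripotency genes in NC against mESC the estimated correlation was -0.045, below the preset value. The camera p still went from 6.34e-08 to 0.0269. Failing that check therefore does not show that a list passed through correlated genes. The genes named were also set by a rule. It took, from called genes with the same direction on both platforms and at least median read level, the 5 with the largest rise and the 5 with the largest fall. It added up to 4 members with the lowest p from each list that had a called member. Pou5f1, Nanog, Pax6, Tubb3, Dnmt3l, Tet1, H19 and Actb were added wherever tested. Genes outside this rule are said to be so, and some genes that the rule takes are not reported here.

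The fits were tested on simulated data in which 200 genes were changed by known folds. For uCG in NC against mESC, with 12610 genes, 95.5% of genes changed 4-fold, 69.7% of those changed 2-fold and 27.3% of those changed 1.5-fold were recovered. For GC in NC against mESC, with 14334 genes, these shares were 90.9%, 46.3% and 7.46%. For hmC in NC against mESC, with 15279 genes, they were 86.2%, 52.3% and 22.7%. In the data 5831 gene bodies were called for hmC, and more changed genes loosen the adjusted p cutoff. The hmC shares from 200 changed genes thus do not carry over to the data and are likely too low there.

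Alternatives were DESeq2 1.42.0, library size without TMM, no filter on low counts, no platform term, the shallow mESC libraries added, covered sites in place of reads, other windows, removal of a trend on site number (loess, span 0.3), GC sites outside CG, for relations between marks at least 10 reads of both, and each library left out. Leaving out a library leaves its stage with 1, which is assumed to vary like the others. Chosen after seeing the data were all genes at their CG-richer end, a minimum ratio of 3, the gene body in place of the gene end, and all reads of the mark in a library as its size, without TMM. The planned library size without TMM was run on reads in the tested features. Correlations were computed on log2(CPM + 1) with scipy 1.17.1 in Python 3.11.15.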

Results

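Unmodified CG sites, hydroxymethylated CG sites and accessible GC sites were counted along the conversion of mouse embryonic stem cells into neuronal progenitors and then neurons. The question was how DNA modification and chromatin accessibility differ between these 3 stages. Each stage had 2 deep 3-X libraries, and mESC also had a shallow 3-X library and 2 shallow 2-X libraries, all on Ion Torrent. The tables listed 20383623 CG sites and 98961922 GC sites. Ion Torrent libraries of mESC, NPC and NC held 7683989, 12024560 and 10636834 uCG reads, and Illumina libraries held 3340758, 2716464 and 2683770. The hmC reads numbered 6997575, 3129703 and 8939443 on Ion Torrent and 5879446, 2720776 and 6223930 on Illumina. GC reads numbered 82042560, 83393468 and 78549767 on Ion Torrent and 7810848, 11335946 and 9280126 on Illumina. Between 4.20% and 17.8% of CG sites had a uCG read in a deep library.

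CG-rich gene ends were the places where unmodified CG reads gathered, and they did so more in later stages. These ends held 5.44% of CG sites. On Ion Torrent they held 12.1% of uCG reads in mESC, 17.6% in NPC and 21.1% in NC, and on Illumina 20.7%, 27.1% and 32.6%. The same order of stages was thus found in both sets of libraries, although the platforms differed by about as much as the stages. The hmC reads were scarce at the same ends, at 1.61%, 2.83% and 1.88% on Ion Torrent and 2.40%, 4.04% and 2.81% on Illumina, with the highest share in NPC on both. Gene bodies, with 43.3% of CG sites, held 50.7% to 55.2% of hmC reads. GC reads per site at CG-rich ends were 1.33 to 2.10 times those over all GC sites. These shares had 2 libraries per stage and were not tested.

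**Figure D1:**
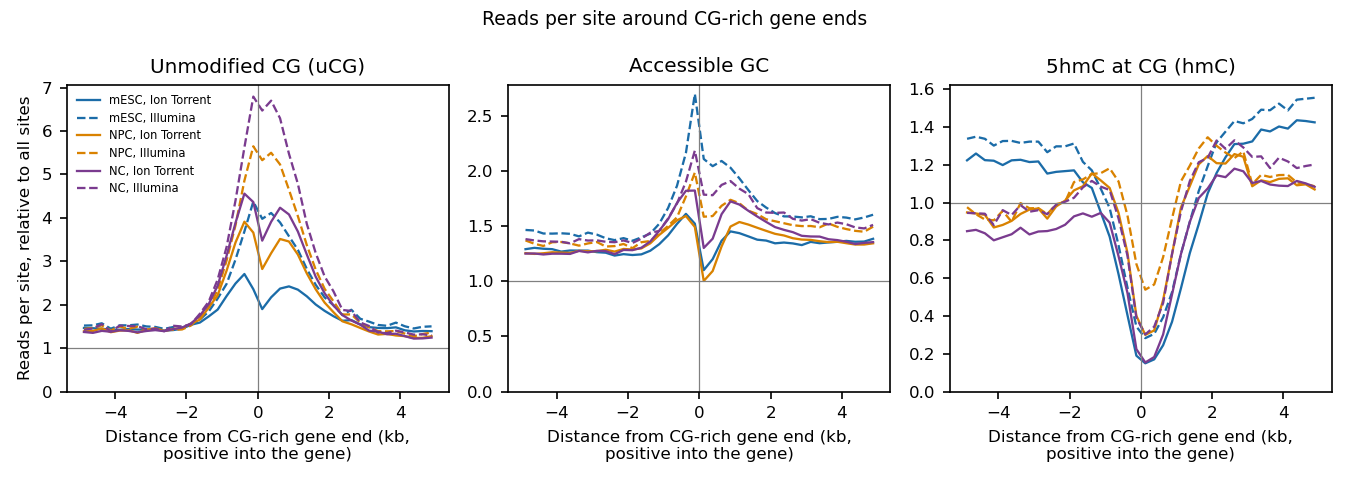
Reads per site relative to all sites of the mark (y axis) against the distance from the CG-rich gene end in kb (x axis, positive into the gene) for the 6 deep libraries, in bins of 250 bp; solid lines are Ion Torrent, dashed lines Illumina. Just outside the end, uCG stood at 2.36 in mESC, 3.66 in NPC and 4.37 in NC on Ion Torrent, while hmC stood at 0.191, 0.401 and 0.225.

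From mESC to NPC, 6 of 23 gene ends of the pluripotency list lost unmodified CG reads relative to other gene ends, and over all genes 172 of 12719 ends lost and 24 gained them, but against all uCG reads of a library 126 lost and 5245 gained them. Folds below are relative to other gene ends unless said otherwise. Pou5f1, a core pluripotency transcription factor (chromosome 17, 35505032 to 35507032), fell from 118.1 ± 0.372 CPM to 47.4 ± 2.05 CPM (mean ± SD, n = 2). Its log2 fold change was -1.33 ± 0.24 (SE), with an edgeR adjusted p of 0.000643, and against all uCG reads it fell by 0.86. Zscan10, Tdh and Tcl1, also of the pluripotency list, fell by 1.87, 1.73 and 1.97 on the log2 scale. Zfp57, a zinc finger protein that maintains imprints, fell by 3.67, and Gnas, an imprinted locus, fell by 1.54. Peg3, a paternally expressed imprinted gene, rose by 1.12, Meg3 by 1.47, the synaptic gene Snap25 by 1.22 and Sox9, a glial and progenitor regulator, by 0.72. Peg3 and Usp29 share most of their window and cannot be told apart.

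In that comparison, edgeR called 196 of 12719 gene ends, 24 higher and 172 lower, all with the same direction on both platforms. Of 23 pluripotency genes, 6 fell and none rose, and adjusted over the list alone 7 fell and 2 rose (camera adjusted p = 6.66e-06). The camera adjusted p was 0.351 with an estimated correlation. Of 21 germline genes, which act in meiosis or piRNA pathways, 2 fell (Sycp1 by 1.87 and Tdrd1 by 1.51), and adjusted over the list alone 12 fell. The germline median was -0.94 (camera adjusted p = 1.53e-09, and adjusted p = 0.351 with an estimated correlation). Neuron and synapse genes had a median of 0.30 with 1 of 25 risen, and adjusted over the list alone 2 risen (adjusted p = 0.00396, and adjusted p = 0.585 with an estimated correlation). Radial glia genes had a median of 0.22 with 1 of 26 risen, and adjusted over the list alone also 1 (adjusted p = 0.0196, and adjusted p = 0.421 with an estimated correlation). Among 25 imprinted genes 3 rose and 2 fell, and adjusted over the list alone 4 rose and 2 fell. Nanog was at -0.50 ± 0.28 and Pax6 at 0.33 ± 0.21, neither called. With all uCG reads of a library as its size, chosen after seeing the data, the median of all genes moved from 0.03 to 0.50 and the calls to 5371, of which 97.7% were higher against 12.2%. The mostly lower split thus holds only relative to other gene ends, whose share of uCG reads was higher in NPC. On that scale 5 of 23 pluripotency genes rose and 5 fell. The count was 47 with DESeq2, of which 0% were higher against 12.2% with edgeR. It was 0 with covered sites in place of reads (226 at an unadjusted p under 0.05). Without the platform term it was also 0 (336 at that level, where 636 were expected by chance). It was 1 without mESC replicate 1, 30 without NPC replicate 1, 39 without mESC replicate 2 and 335 without NC replicate 2.

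From NPC to NC, no gene end was called for uCG. The edgeR test gave 0 of 12719, with 714 at an unadjusted p under 0.05 where 636 were expected by chance, and DESeq2 gave 0 with 222 at that level. With all uCG reads of a library as its size it was also 0 (2494 at that level), while the median of all genes moved to 0.255. Pou5f1 stayed near its NPC level (log2 fold change 0.06 ± 0.24), Nanog was at -0.70 ± 0.29 and Pax6 at 0.15 ± 0.19. Of the 11 lists, germline had a camera adjusted p of 0.031 with a median of -0.20 and 0 of 21 members called, also 0 adjusted over the list alone; its adjusted p = 0.98 with an estimated correlation. Fold changes on the platforms were almost unrelated across genes (Spearman 0.027). Without NPC replicate 1 the count was 1.

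From mESC to NC, 7 of 23 pluripotency and 10 of 21 germline gene ends lost unmodified CG reads relative to other gene ends; against all uCG reads of a library 6 of 23 pluripotency genes fell and 10 rose, and 6 of 21 germline genes fell and 1 rose. Zscan10 fell from 73.2 ± 10.8 CPM to 16.5 ± 2.82 CPM (log2 fold change -2.13 ± 0.34, edgeR adjusted p = 4.76e-05), Tcl1 fell by 2.28, Tdh by 1.9, Pou5f1 by 1.27 and Nanog by 1.20. The germline genes that fell included Sycp1, a protein of the synaptonemal complex, by 1.88, Tex14 by 1.18, Tex19.1 by 2.50 and Stk31 by 3.01. Zfp57 fell by 5.86, on 53 and 20 reads in the mESC libraries against 0 and 2 in NC. Fabp7, a fatty acid binding protein of radial glia, rose by 2.30 ± 0.50, from 7.50 ± 1.35 CPM to 37.9 ± 0.907 CPM, and the glutamate receptor gene Gria1 rose by 2.05 ± 0.57. The homeobox genes Irx2 and Gsx2 rose by 1.1 and 0.84. Rbfox3, a marker of mature neurons, fell by 1.55 at its CG-rich end, against the direction of its list. Whether that end is its transcription start is not known, and over its body uCG rose by 0.65.

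The edgeR test called 533 of 12719 gene ends from mESC to NC, 104 higher and 429 lower relative to other gene ends. With all uCG reads of a library as its size the median of all genes moved from 0.04 to 0.77 and the calls to 9441, of which 97.7% were higher against 19.5%, so the mostly lower split depends on the scaling. On that scale Pou5f1 fell by 0.54 and Zscan10 by 1.4, and Nanog was at -0.46 and no longer called. The germline list had a median of -1.25, with 14 fallen when adjusted over the list alone (camera adjusted p = 9.75e-14, and adjusted p = 0.286 with an estimated correlation). Of 23 pluripotency genes 7 fell, and adjusted over the list alone 9 fell and 1 rose (adjusted p = 2.27e-06, and adjusted p = 0.286 with an estimated correlation). Neuron and synapse genes had a median of 0.38, with 2 of 25 risen and 1 fallen, and adjusted over the list alone 3 and 1 (adjusted p = 0.00572, and adjusted p = 0.682 with an estimated correlation). Radial glia genes had a median of 0.28, with 2 of 26 risen, and adjusted over the list alone 3 risen and 1 fallen (adjusted p = 0.00568, and adjusted p = 0.39 with an estimated correlation). The count was 194 with DESeq2, of which 2.58% were higher against 19.5% with edgeR, 9 with covered sites and 0 without the platform term (565 at an unadjusted p under 0.05). Without mESC replicate 1 edgeR called 0 (1100 at that level); without NC replicate 1 it called 85, without mESC replicate 2 127, without NC replicate 2 302 and without NPC replicate 2 832.

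Accessibility at gene ends, read from GC sites, was lower at few genes in NPC than in mESC. Pdk4, a kinase that inhibits pyruvate dehydrogenase, fell by 1.21 ± 0.22, the chromatin remodeller gene Chd9 by 1.11 ± 0.21 and the coatomer gene Copg1 by 1.1 ± 0.22. These were the 3 calls among 14385 gene ends, with edgeR adjusted p from 0.0335 to 0.0401. Over the alternatives Pdk4 was not called in 11 of 19, Chd9 in 10 of 19 and Copg1 in 10 of 18, though none changed sign. Counts from other fits below are thus not always of these genes. Pou5f1 was at -0.61 ± 0.22 and Nanog at -0.74 ± 0.25, neither called. Of 23 pluripotency genes none was called, and adjusted over the list alone 3 fell, with a median of -0.21 (camera adjusted p = 0.00481, and adjusted p = 0.565 with an estimated correlation). DESeq2 called 0 (436 at an unadjusted p under 0.05). With all GC reads of a library as its size edgeR also called 0 (830 at that level), and the median of all genes moved to -0.127. The edgeR count was 1 without mESC replicate 1, 5 without NPC replicate 1, 27 without NC replicate 1, 0 without mESC replicate 2 (474 at that level), 0 without NPC replicate 2 (858) and 23 without NC replicate 2.

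From NPC to NC, no gene end was called for GC. The edgeR test gave 0 of 14385, with 607 at an unadjusted p under 0.05 where 719 were expected by chance, and DESeq2 gave 0 with 252. Nanog was at -0.62 ± 0.27, Pou5f1 at -0.39 ± 0.23, Pax6 at -0.04 ± 0.24 and the imprinted H19 at 0.16 ± 0.24. With all GC reads of a library as its size the count was also 0 (878) and the median of all genes moved to 0.207. None of the 11 lists passed camera. By fry, neuron and synapse genes (median 0.28) and pluripotency genes (median -0.15) had an adjusted p of 0.0402 each, with 0 of 26 and 0 of 23 members called, also 0 adjusted over the list alone. For both, camera gave an adjusted p = 0.506 with an estimated correlation. Without NPC replicate 1 the count was 3, and without NC replicate 1 it was 5.

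From mESC to NC, 3 of the 14 gene ends that lost accessibility belonged to pluripotency genes. Nanog, a core pluripotency factor, fell from 116.2 ± 36.6 CPM to 43.7 ± 22.4 CPM (log2 fold change -1.36 ± 0.27, edgeR adjusted p = 0.0146). Klf2, also a pluripotency factor, fell by 1.32 ± 0.25 and the growth factor gene Gdf3 by 1.21 ± 0.26. Copg1 and Hmces, whose windows overlap, fell by 1.56 and 1.38, and Wdtc1 by 1.44, all more than Nanog. Itgb8, an integrin subunit gene, was the 1 gene called higher (1.08 ± 0.22, from 70.4 ± 17.1 CPM to 161.0 ± 8.59 CPM). Over the alternatives Nanog was not called in 9 of 18, Klf2 in 8 of 17 and Gdf3 in 9 of 18. Wdtc1 was not called in 8 of 18 and Itgb8 in 10 of 19, against 3 of 18 for Copg1 and 5 of 18 for Hmces. None of these changed sign. Pou5f1 was at -1.0 ± 0.23 with an adjusted p of 0.062.

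The edgeR test called 15 of 14385 gene ends in that comparison, 14 of them lower. Of 23 pluripotency genes 3 fell, and adjusted over the list alone 4 fell, with a median of -0.39 (camera adjusted p = 6.97e-07, and adjusted p = 0.282 with an estimated correlation). Neuron and synapse genes had a median of 0.28 with 0 of 26 called, also 0 adjusted over the list alone (adjusted p = 0.000808, and adjusted p = 0.282 with an estimated correlation). Germline genes had a GC median near 0 (0.02), with 0 of 21 called. The count was 4 with DESeq2, 2 with all GC reads of a library as its size and 0 both without the platform term (471 at an unadjusted p under 0.05) and with covered sites (386). Without mESC replicate 1 it was 0 (742), without mESC replicate 2 3, without NC replicate 2 37, without NPC replicate 1 50 and without NPC replicate 2 52.

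From mESC to NPC, 19 of 34 neuron and synapse, 10 of 23 radial glia, 12 of 18 Hox and 16 of 24 imprinted genes gained hmC reads over their bodies relative to other gene bodies, as did 7 of 17 mesoderm and endoderm genes. Dach1, a transcription factor gene, rose from 36.7 ± 9.65 CPM to 508.9 ± 19.6 CPM (log2 fold change 3.8 ± 0.14, edgeR adjusted p = 3.88e-29). The neurexin gene Nrxn3 rose by 2.60, Map2, a microtubule protein of dendrites, by 2.16, Syt1 by 1.57 and Gria1 by 1.81. Pax6, a regulator of radial glia, rose by 1.82 ± 0.20 and Gli3 by 1.69. Hoxb3, Hoxd3, Hoxa3 and Hoxc4 rose by 2.24, 1.73, 1.5 and 1.96, and Trim71, of the pluripotency list, rose by 2.21. Dnmt1, the maintenance methyltransferase, fell from 144.2 ± 14.8 CPM to 56.4 ± 10.2 CPM (-1.36 ± 0.18), and Pfas, Aida and Rrn3 fell by 3.17, 2.91 and 2.75. Small bodies with few reads also moved, such as Pou5f1 (1 and 4 reads in mESC, 20 and 8 in NPC).

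In that comparison edgeR called 5767 of 15551 gene bodies, 3111 higher and 2656 lower. Of 34 neuron and synapse genes 19 rose and none fell, and adjusted over the list alone 19 rose and 1 fell (camera adjusted p = 2.82e-08, and adjusted p = 0.412 with an estimated correlation). Of 18 Hox genes 12 rose, also 12 adjusted over the list alone, with a median of 1.62 (adjusted p = 1.4e-05, and adjusted p = 0.298 with an estimated correlation). Of 24 imprinted genes 16 rose, also 16 adjusted over the list alone (adjusted p = 1.02e-05, and adjusted p = 0.255 with an estimated correlation); Usp29 and Plagl1 rose by 1.92 and 1.65. Of 23 radial glia genes 10 rose, also 10 adjusted over the list alone (adjusted p = 0.000138, and adjusted p = 0.255 with an estimated correlation). Of 17 mesoderm and endoderm genes 7 rose and none fell, also 7 adjusted over the list alone, with a median of 0.47, but the list did not pass camera (adjusted p = 0.343, and adjusted p = 0.694 with an estimated correlation). Among 16 housekeeping genes 4 rose and 4 fell, and adjusted over the list alone 5 rose and 4 fell. Without TMM the median of all genes moved from -0.09 to -0.46 and the calls to 7144, of which 26.2% were higher against 53.9% with TMM, so directions here are relative to the TMM baseline. With all hmC reads of a library as its size they were -0.57, 7787 and 20.1%. DESeq2 called 3756, of which 67.5% were higher, and edgeR called 2900 without mESC replicate 1 and 3189 without mESC replicate 2.

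From NPC to NC, 5 of 18 Hox, 3 of 23 radial glia and 2 of 17 mesoderm and endoderm genes lost hmC reads relative to other gene bodies. Hoxb3 fell from 253.0 ± 61.4 CPM to 101.2 ± 61.1 CPM (log2 fold change -1.41 ± 0.16, edgeR adjusted p = 3.24e-08), and Hoxd3, Hoxc4 and Hoxa3 fell by 1.34, 1.21 and 1.12. Pax6 fell by 0.90 ± 0.19, Lhx2, a forebrain regulator, by 1.1 and Slc1a3, a glutamate transporter of glia, by 0.46. Gata4, an endoderm regulator, fell by 1.04, and Zic4 and Onecut3 by 1.68 and 1.45. Rbfox3 rose by 0.42 ± 0.09, while Tbr1, a transcription factor of cortical neurons, fell by 1.35. Stard3nl and Carmil2 rose by 1.69 and 1.62.

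The edgeR test called 866 of 15551 gene bodies, 454 higher and 412 lower. Of 18 Hox genes 5 fell, and adjusted over the list alone 10 fell, with a median of -1.16 (camera adjusted p = 3.1e-15, and adjusted p = 0.191 with an estimated correlation). Of 23 radial glia genes 3 fell, and adjusted over the list alone 10 (adjusted p = 8.36e-06, and adjusted p = 0.191 with an estimated correlation). Of 17 mesoderm and endoderm genes 2 fell, and adjusted over the list alone 6 (adjusted p = 8.36e-06, and adjusted p = 0.257 with an estimated correlation). Of 24 imprinted genes 4 fell and 1 rose, and adjusted over the list alone 5 and 1 (adjusted p = 0.0132, and adjusted p = 0.257 with an estimated correlation). Of 29 pluripotency genes 2 fell, and adjusted over the list alone 3 (adjusted p = 0.0152, and adjusted p = 0.29 with an estimated correlation). DESeq2 called 200 (36.5% higher, against 52.4% in the edgeR fit). With all hmC reads of a library as its size edgeR called 1152, of which 71.0% were higher. With the shallow mESC libraries added edgeR called 0 (1188 at an unadjusted p under 0.05). These included the 2-X library for hmC and GC, with 355926 hmC reads, of which 13.0% lay at CG-rich gene ends. In the shallow 3-X library that share was 1.48%. A fit with only the shallow 3-X library added was not run, so the 0 may rest on the 2-X library. The count was 413 without mESC replicate 1, 506 without NPC replicate 1, 73 without NC replicate 1, 415 without mESC replicate 2, 1623 without NPC replicate 2 and 306 without NC replicate 2.

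From mESC to NC, 19 of 34 neuron and synapse genes gained hmC reads over their bodies, relative to other gene bodies. Erbb4, a neuregulin receptor gene, rose from 64.4 ± 2.68 CPM to 408.1 ± 106.8 CPM (log2 fold change 2.66 ± 0.14, edgeR adjusted p = 5.38e-23), Nrxn3 by 2.67, Map2 by 2.05 and Gria1 by 1.93. Dach1 rose by 3.25 and Gad2, which makes GABA, by 1.64. Gad2 was the 1 of 12 inhibitory neuron genes called in this comparison, and the median of that list was -0.11 (camera adjusted p = 0.956). Usp29, Dlk1 and Kcnq1, of the imprinted list, rose by 1.16, 1.66 and 0.76. Dnmt1 fell by 1.34, Mbd1 by 1.92 and Tet1, which makes 5hmC, by 0.37 ± 0.15. Tet3 was at 0.33 ± 0.11, called here but at -0.04 without TMM and at -0.08 against all hmC reads. The NMDA receptor gene Grin1 and the vesicular glutamate transporter gene Slc17a7, named after their values were seen, fell by 1.08 and 1.09 against the direction of their list.

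The edgeR test called 5831 of 15551 gene bodies from mESC to NC, 3194 higher and 2637 lower. Of 34 neuron and synapse genes 19 rose and 2 fell, and adjusted over the list alone 21 rose and 2 fell (camera adjusted p = 4.55e-09, and adjusted p = 0.561 with an estimated correlation). Of 24 imprinted genes 14 rose and 2 fell, the same numbers as adjusted over the list alone (adjusted p = 0.000748, and adjusted p = 0.561 with an estimated correlation). Among 18 Hox genes 5 rose and 1 fell, and adjusted over the list alone 4 and 1, which did not pass camera (adjusted p = 0.591). Of 23 radial glia genes 11 rose and 2 fell, and adjusted over the list alone 11 and 3. For them camera gave an adjusted p of 0.153, or 0.561 with an estimated correlation, and fry 0.0262. Of 20 germline genes 4 fell and 0 rose, also 4 adjusted over the list alone. The germline list passed fry (adjusted p = 0.0473) but not camera (adjusted p = 0.377, and adjusted p = 0.679 with an estimated correlation). Markers of astrocytes and oligodendrocytes did not move together: of 13, 2 rose and 3 fell, also 2 and 3 adjusted over the list alone. Without TMM the median of all genes was -0.44 against -0.07, and 24.6% of 7130 calls were higher against 54.8%. With all hmC reads of a library as its size the median was -0.48, and 22.1% of 7388 calls were higher. With TMM the neuron and synapse, imprinted and radial glia lists had medians of 0.75, 0.61 and 0.61. Their counts above hold relative to the TMM baseline and are not given here on the other scales. DESeq2 called 3532, of which 68.0% were higher. The count was 2665 without mESC replicate 1, 3072 without NC replicate 1, 2816 without mESC replicate 2 and 3815 without NC replicate 2.

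**Figure D2:**
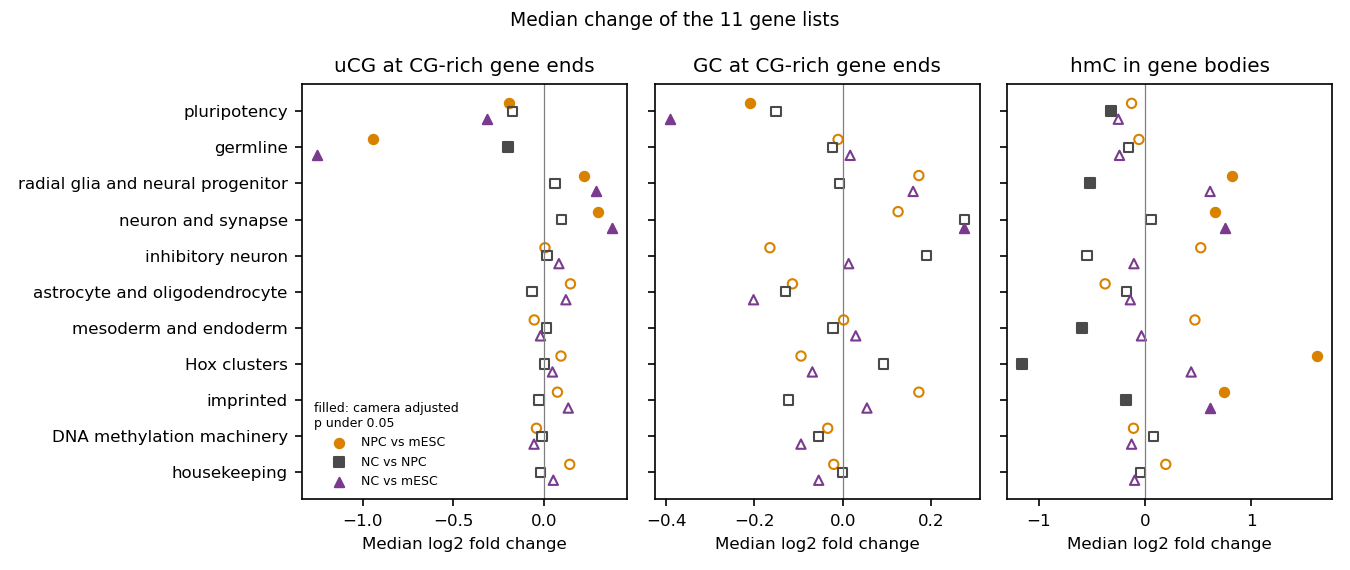
Median log2 fold change (x axis) of the members of the 11 gene lists (y axis) for uCG and GC at CG-rich gene ends and hmC in gene bodies, relative to the other ends or bodies; orange circles, grey squares and purple triangles are the 3 comparisons, and filled symbols have a camera adjusted p under 0.05 at the preset correlation. The germline list stands at -1.25 for uCG in NC against mESC, and the Hox list at 1.62 and then -1.16 for hmC.

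**Figure D3:**
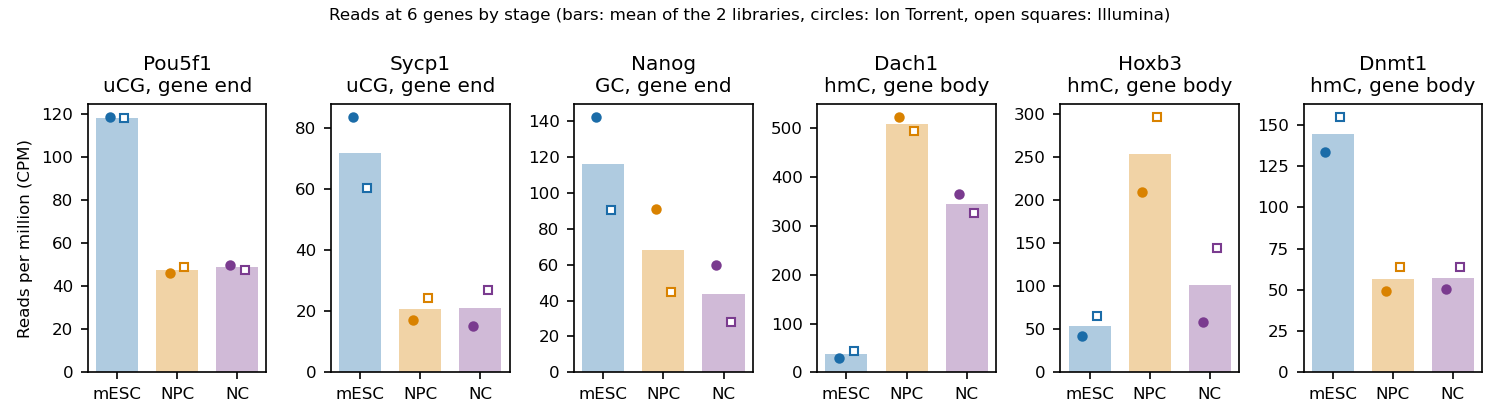
Read level in CPM (y axis, from 0) at 6 genes by stage (x axis), with bars for the mean of 2 libraries, circles for Ion Torrent and open squares for Illumina. Pou5f1 uCG stood at 118.1 CPM in mESC and 47.4 in NPC, and Dach1 hmC at 36.7 and 508.9.

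Over all 9 comparisons, 23 of 99 pairs of list and comparison passed camera at the preset correlation, 0 passed with an estimated correlation (lowest adjusted p 0.191) and 8 passed fry. Camera with an estimated correlation had little power at 2 residual degrees of freedom, so its count of 0 decides little. In the 23 that passed, the median, the mean and the test had 1 sign. In others they differed, as for pluripotency genes in hmC from mESC to NPC, with a median of -0.13, a mean of 0.23 and camera pointing up. The DNA methylation machinery did not pass camera in any comparison; in hmC from mESC to NC 2 of its 16 genes rose and 3 fell, also 2 and 3 adjusted over the list alone (camera adjusted p = 0.591). Inhibitory neuron genes did not pass camera in any comparison either; in hmC from mESC to NPC 3 of 12 rose and 1 fell, also 3 and 1 adjusted over the list alone (camera adjusted p = 0.495), and the list passed fry (adjusted p = 0.0175).

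Libraries of a stage made on different platforms ranked gene bodies alike in hmC, with a mean Spearman correlation across genes of 0.968 ± 0.0198 (SD, n = 3 stages). For uCG at gene ends it was 0.821 ± 0.0111 and for GC 0.730 ± 0.0394. Gene bodies differ widely in size. Windows at gene ends have the same length but differ in site number, such as 23 CG sites at Fabp7 and 144 at Sox9. Reads were not divided by sites, so site number may carry part of these correlations for bodies and ends. The values thus do not rank the marks: in 10 kb windows they were 0.878 for hmC, 0.781 for uCG and 0.939 for GC. Genes are not independent replicates, and no p-value is given. Changes between stages were less alike: the fold changes of both platforms correlated across genes at 0.681 and 0.772 for hmC in NPC and NC against mESC, at 0.283 and 0.384 for uCG, and at 0.147 and 0.171 for GC. In NC against NPC they correlated at 0.228 for hmC, with the same sign in 59.8% of genes, at 0.0266 for uCG and at 0.0406 for GC.

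The 2-X library for uCG and GC was set against the 3-X libraries of mESC, to ask whether a further tag changes the reading. Its uCG reads at gene ends correlated at 0.915 with the shallow and 0.905 with the deep 3-X Ion Torrent library, and the latter pair with each other at 0.916. The 2-X library for hmC and GC had 355926 hmC reads and correlated at 0.793 and 0.796, where the pair of 3-X libraries had 0.971. In that 2-X library 13.0% of hmC reads lay at CG-rich gene ends, against 1.48% and 1.61% in the shallow and deep 3-X libraries. Reads were not divided by sites here either. Each kind had 1 library, so no difference was tested.

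Within each deep library, gene ends with more GC reads per site also had more uCG reads per site. Both marks came from the same library and no control for coverage was used. Shared coverage was thus not told apart from a relation between marks, here and for gene bodies. The Spearman correlation across 14914 genes was 0.533 ± 0.118 (SD, n = 6 libraries), from 0.382 in NPC to 0.669 in mESC. On Ion Torrent it was 0.541 to 0.669 and on Illumina 0.382 to 0.585. In gene bodies, hmC and uCG reads per site correlated at 0.475 ± 0.0839 across 17581 genes, from 0.386 to 0.627. Over genes with at least 10 reads of both marks, the first relation had a mean of 0.417 and the second of 0.403. The first was then 0.233 in the Illumina NC library (0.397 over all genes) and 0.242 in the Illumina NPC library (0.382), and the second 0.261 in the Illumina NC library (0.451).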

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

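Of the tests below, those on reads at the same ends, on a left-out mESC library, on gene bodies and on single Hox clusters were chosen after the result was seen.

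Both of the authors' region tables hold regions with no stage, and no comparison above used them. The table marked idGC had 663311 of these and the table marked idT 751741. Those in the first table had a median width of 124 bp and at least 1 bp of overlap with 87.3% of the 14914 CG-rich gene ends. For the second these values were 144 bp and 89.7%. Of the regions with no stage, 4.47% and 3.88% lay at these ends, and the overlap expected by chance was not computed.

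In NC against mESC 10 of 21 germline gene ends lost uCG reads, relative to other gene ends (6 of 21 against all uCG reads of a library, where 1 rose), and the median of the list lay 1.29 below that of all genes (-1.29). With a trend on the number of CG sites removed it was -1.20, which argues against that trend. Without the Ion Torrent mESC library or without the Ion Torrent NC library 0 germline genes were called, but the difference was still -0.882 and -1.36, which argues against either library as the whole source. GC reads showed no shared loss at the same ends, as their germline median differed from that of all genes by 0.0095. However, GC fold changes of the platforms correlated across genes at only 0.171. In mESC 53.0% of genes on Ion Torrent and 70.2% on Illumina had more GC reads per site at their CG-richer end. GC reads were thus a weak measure of these ends, and a closing was not excluded. Gain of methylation at these ends as stem cells differentiate may explain the loss of uCG reads and stays a hypothesis. A uCG count cannot separate methylation from 5hmC, and stage is the design's own difference. The hmC reads at germline gene ends were not compared.

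More gene bodies changed in hmC than gene ends in uCG, but with all reads of the mark as library size uCG gave 5371 calls against 7787 for hmC in NPC against mESC and 9441 against 7388 in NC against mESC, so the contrast depends on scaling within the features. Thinning hmC reads to the number of uCG reads at gene ends still left 4548 calls in NPC against mESC, against 196 for uCG, which argues against read depth. Over gene bodies, uCG gave 2323 calls in NPC against mESC, fewer than 5767 for hmC by more than 1.5 times, which argues against the feature as the whole source there, but 4261 in NC against mESC, within 1.5 times of 5831. Bodies differ from ends in size, reads, place and genes tested (15608 against 12719), so in NC against mESC the feature may account for the contrast, and which of these matters stays open.

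Of 39 listed Hox genes 18 had a tested body, of which 12 gained hmC reads from mESC to NPC and 5 lost them from NPC to NC. Both comparisons share the NPC libraries, whose chance deviations push them apart. Of 10000 random lists matched on the number of CG sites and read level, 0% had an NPC median as high (the highest was 1.00, against 1.62). These lists were not matched on CG sites per length. The share of hmC reads at CG-rich gene ends was also highest in NPC, at 2.83% on Ion Torrent and 4.04% on Illumina. A rise shared by CG-dense sequence was thus not tested. With each library left out in turn the lowest Hox median relative to all genes was 1.45, and 4 of the 4 clusters had a median over 0.5. The clusters were uneven: 5 of 5 Hoxb and 4 of 4 Hoxd genes rose, against 2 of 6 Hoxa and 1 of 3 Hoxc genes. The Hoxa median was 0.571, close to that limit. Random lists take genes one at a time while Hox genes are neighbours, so a change of domains that hold many genes may be what was measured, and no biological explanation beyond stage was tested.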

How the results depend on the processing

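The alternatives with all genes at their CG-richer end, with an end ratio of at least 3, with the gene body in place of the gene end and with all reads of the mark as library size were chosen after seeing the data. For 271 values of named genes, 4317 recomputed values were compared: 3445 kept direction and side of the threshold, 725 lost the call, 118 gained it and 29 turned, where a change of sign was counted only if the gene was called in either setting. Counts of calls below are for NPC against mESC, NC against NPC and NC against mESC; those not named stayed within 1.5 times. DESeq2 gave 47 and 194 for uCG (first and last comparison), 0 and 4 for GC, and 3756, 200 and 3532 for hmC. Without the platform term edgeR gave 0 and 0 for uCG, 0 and 0 for GC, and 244 for hmC in NC against NPC. Covered sites gave 0 and 9 for uCG, 0 and 0 for GC, and 284 for hmC in NC against NPC, of which 34.2% were higher against 52.4%. Windows of 500 bp gave 48 and 176 for uCG and 1 and 3 for GC. Added shallow mESC libraries gave 0 and 9 for GC and 3215, 0 and 3122 for hmC. For hmC these included the 2-X library, whose reads were spread unlike those of the 3-X libraries. The whole gene span gave 484 for hmC in NC against NPC. All reads of the mark as library size gave 5371 and 9441 for uCG, of which 97.7% and 97.7% were higher against 12.2% and 19.5%, and 0 and 2 for GC. For hmC the higher share was then 20.1%, 71.0% and 22.1% against 53.9%, 52.4% and 54.8%. There Gadd45a (0.16) and Sox1 (0.33) turned for uCG in NC against mESC, and for hmC Tet1 (-0.47) in NPC against mESC and Tet3 (-0.0812) in NC against mESC. The counts of 0 above had 224 to 1188 genes at an unadjusted p under 0.05, over edgeR and DESeq2. Those below the number expected by chance give no evidence of changes short of the threshold. All genes at their CG-richer end gave 441 and 1054 for uCG and 26 for GC in NC against mESC, and a ratio of 3 gave 108, 271 and 5. With the trend on site number removed, the hmC counts were 4988 in NPC against mESC and 4962 in NC against mESC, but 119 and 145 gene bodies called in both fits had opposite signs.

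Gene bodies in place of gene ends gave 2323, 187 and 4261 calls for uCG and 1576 and 2680 for GC, where size, place and the genes tested all differ. There uCG turned in NPC against mESC for Ino80d (-0.71), Ints3 (-0.13), Pou5f1 (0.10), Zfp57 (0.18), Sycp1 (0.27), Tdrd1 (0.69), Gnas (0.50), Mest (0.57) and Rbfox3 (0.55). In NC against mESC it turned for Ttc33 (-1.003), Pou5f1 (0.46), Tet1 (-0.58), Zfp57 (0.49), Mbd1 (-0.73), Tet2 (-0.67), Sycp1 (0.048), Tex14 (0.45), Gnas (1.00), Hnf4a (0.33), Rbfox3 (0.65) and Sox1 (1.104), and GC for Pax6 (0.42). A turn needed a call in either setting, not in both. Both were called for Ino80d, Tdrd1, Gnas and Mest in NPC against mESC, and for Ttc33, Tex14, Gnas and Rbfox3 in NC against mESC. The body was not called for Ints3, Pou5f1, Zfp57 and Sycp1 in NPC against mESC. In NC against mESC it was not called for Pou5f1, Zfp57, Mbd1, Sycp1 and Hnf4a. The end was not called for Tet1 and Tet2 in NC against mESC or Rbfox3 in NPC against mESC. Directions at the end thus do not carry over to the body, and opposite changes stand only where both were called. Tet3 in hmC turned in NC against mESC without TMM (-0.0415) and with the trend on site number removed (-0.10), and in NC against NPC with covered sites (-0.00278).

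With each library left out in turn, calls ranged from 1 to 335, 0 to 1 and 0 to 832 for uCG, from 0 to 27, 0 to 5 and 0 to 52 for GC, and from 2900 to 5393, 73 to 1623 and 2665 to 7289 for hmC. Of the 99 pairs of list and comparison, 0 passed camera with an estimated correlation, which had little power, and 8 passed fry. In 10 kb windows the platforms correlated at 0.781 for uCG, 0.878 for hmC and 0.939 for GC; the 2-X library correlated with the shallow and deep 3-X libraries at 0.887 and 0.852 for uCG and at 0.526 and 0.549 for hmC. For these changes the cause was not tested. Other pseudocounts cannot move a rank correlation, and autosomes alone were not run, since all sites lie on autosomes. In simulated data for NPC against mESC, 33.3% of 2-fold changes were recovered for GC (14334 genes), 47.0% for hmC (15267 genes) and 74.6% for uCG (12613 genes). For GC and uCG, weaker changes were thus often not detectable. The hmC share does not carry over, since 200 genes were changed there while 5767 were called in the data, where the cutoff was less strict.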

Other observations

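The tests here, on uCG and GC over gene bodies, were chosen after seeing the data. Directions are relative to other gene bodies. Bodies held 45.6% of uCG reads in mESC and 40.4% in NC on Ion Torrent, and 43.6% and 37.2% on Illumina. Of all 15608 bodies tested for uCG, 1491 rose and 832 fell from mESC to NPC, and 2622 and 1639 from mESC to NC. No trend on site number was removed and no other library size was used. A rise shared by CG-dense bodies was thus not tested. Hox gene bodies also gained unmodified CG reads: from mESC to NPC 19 of 25 rose and none fell, and adjusted over the list alone 24 rose, with a median of 0.97 (camera adjusted p = 4.96e-20, and adjusted p = 0.152 with an estimated correlation). From mESC to NC 22 of 25 rose, and adjusted over the list alone 24, with a median of 1.30 (adjusted p = 8.02e-23, and adjusted p = 0.123 with an estimated correlation). For hmC from mESC to NC the Hox median was 0.43; the difference between the marks was not tested. Radial glia genes rose in 19 of 23 cases from mESC to NC, and adjusted over the list alone 21 rose and 1 fell, with a median of 1.02 (adjusted p = 8.01e-17, and adjusted p = 0.123 with an estimated correlation). Neuron and synapse genes rose in 22 of 33 cases and 1 fell, and adjusted over the list alone 23 rose and 1 fell (adjusted p = 4.59e-11, and adjusted p = 0.123 with an estimated correlation). Inhibitory neuron genes rose in 9 of 12 cases, also 9 adjusted over the list alone, with a median of 1.08 (adjusted p = 1.01e-09, and adjusted p = 0.147 with an estimated correlation). Lists outside the neural lineage passed camera as well: 7 of 16 mesoderm and endoderm genes rose, also 7 adjusted over the list alone (adjusted p = 1.74e-05, and adjusted p = 0.123 with an estimated correlation). Of 25 imprinted genes 12 rose, and adjusted over the list alone 13 (adjusted p = 1.39e-05, and adjusted p = 0.123 with an estimated correlation). Other lists went down or did not follow their gene ends. From mESC to NPC 9 of 30 pluripotency genes fell and 3 rose, and adjusted over the list alone 11 fell and 4 rose (adjusted p = 0.0079, and adjusted p = 0.161 with an estimated correlation). Of 16 genes of the DNA methylation machinery 2 fell, also 2 adjusted over the list alone (adjusted p = 0.0077, and adjusted p = 0.171 with an estimated correlation). From mESC to NC 3 of 21 germline genes rose and 0 fell with edgeR, and adjusted over the list alone 2 rose (camera adjusted p = 0.932).

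For GC from mESC to NC, edgeR called 2680 of 17070 gene bodies. Of 34 neuron and synapse genes 7 rose and 1 fell, and adjusted over the list alone 8 rose and 2 fell, with a median of 0.16 (camera adjusted p = 0.00943, and adjusted p = 0.516 with an estimated correlation). Of 30 pluripotency genes 3 fell, also 3 adjusted over the list alone, with a median of -0.17 (adjusted p = 0.0293, and adjusted p = 0.513 with an estimated correlation). Radial glia genes rose in 6 of 24 cases and 1 fell, and adjusted over the list alone 8 and 1, with a median of 0.26 (camera adjusted p = 0.00943, and adjusted p = 0.516 with an estimated correlation). Of 25 Hox genes 4 rose, also 4 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.0291, and adjusted p = 0.516 with an estimated correlation).

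The CG-richer end was also the end with more uCG reads per site for 81.1% to 96.2% of genes with at least 10 reads at both ends together, and with more GC reads per site for 53.0% to 70.2%, over the 6 deep libraries. The authors' idGC regions numbered 1026165 in mESC, 1012079 in NPC and 975132 in NC, and overlapped 86.7%, 86.0% and 87.7% of CG-rich gene ends by at least 1 bp. Of these regions 2.83%, 2.84% and 3.19% lay at such ends, and the overlap expected by chance was not computed.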
